A study of Escherichia coli str. K-12 substr. MG1655 with 8 samples.

How the data were processed

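RNA was measured in Escherichia coli K-12 MG1655 with a repaired rph gene, in a wild-type strain and in a strain deleted for hfq, the gene of the RNA chaperone Hfq, with 4 libraries each. Per the labels' protocols, cells grew in a rich defined medium to mid-log phase, total RNA was extracted with hot phenol, and libraries were made with a kit designed for small RNAs. The deposited files give whole-number read counts per gene, 1 value per gene symbol and library, for the same 4451 genes. Per the submitters' processing notes, the tools were cutadapt, Bowtie2 and HTSeq. Their versions, settings and genome build are not given in the sources used here. Whether counting used strand is not stated either, so reads of a gene and of an antisense partner may not be told apart, and genes that overlap are uncertain. Genes of rRNA, tRNA and insertion sequences have near-identical copies, and how reads were shared between copies is not stated.

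Gene symbols were paired with the RefSeq annotation ASM584v2 for gene classes and neighbours only. Of the 4451 symbols, 4237 matched a current symbol, 200 matched a synonym, and 14 matched neither. No coordinates are given, because no build is named for the files.

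Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its defaults, a minimum count of 10 and a minimum total of 15, which left 1705 genes. Library sizes were scaled by TMM, and the groups were compared by the robust quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A second count required a change of at least 2-fold. Normalised read counts are given as CPM on TMM library sizes. Standard errors of log2 fold changes were derived from the test's F statistic. Gene lists were fixed before the data were examined, 28 in all. The 23 with at least 5 genes tested were compared with the other genes by camera in limma 3.58.1, on log2 values with a prior count of 2 and a preset correlation of 0.01, and repeated with an estimated correlation. Shares of the library total in each RNA class were compared by an exact permutation test, two-sided, over 70 assignments, whose smallest p is 0.0286.

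Named genes followed a rule also set before the data were examined. It took hfq and its neighbours, and the 10 genes that rose most and the 10 that fell most. These had to pass the threshold without overlap between the groups, with a mean of at least 20 reads in the higher group, and rRNA, tRNA and insertion sequence genes were left out. It added up to 3 members of each list with the lowest adjusted p past the threshold, and tested small RNAs that bind Hfq. Other genes named below were chosen after their values were seen.

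Totals per library ran from 583829 to 810238 reads, of which 132550 to 216776 lay outside rRNA genes. A count of 0 allows up to 3 reads, or 3.70 to 5.14 CPM of the library total, for counting error only. The labels do not say that the 4 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

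Replicates were compared by a chi-square test over genes with at least 10 reads in the pair. The test found no difference past sampling noise between deletion libraries C and D over 2188 genes (chi-square of 1.04 per degree of freedom, p = 0.0983) or B and D over 2311 genes (1.05, p = 0.0551), while B and C differed (p = 2.56e-13), as did the remaining pairs of both groups. Over protein-coding genes alone, B and C did not differ past the threshold either (chi-square p = 0.139). C and D, the closest pair over all genes, were counted as 1 sample in means and SDs, leaving 3 for the deletion. This was not done where all 4 deletion libraries are named. The tests and the fold changes used all 8 libraries as designed. Summing C and D, B and D, or B, C and D was tried as well, an alternative chosen after seeing the data.

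The edgeR and camera steps were tested on simulated data for this comparison, with counts drawn for the 1705 genes. Of the changed genes, 62.7% were recovered at 1.5-fold, 82.1% at 2-fold and 86.4% at 4-fold, and 4.73% of the calls were unchanged genes. Each gene was drawn independently, with the gene-wise dispersion that edgeR estimated. The median of these was 0.00222, against 0.0256 for the final values in DESeq2. The rates therefore hold for that spread only, and camera was not tested on correlated genes. Alternatives were DESeq2 size factors, upper-quartile scaling and library totals in edgeR, no filter, a filter of 20 reads in 4 libraries, removal of rRNA and tRNA genes, each library left out, a replicate block, the DESeq2 1.42.0 Wald test, limma-voom, and other list tests.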

Results

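The data comprise 8 RNA libraries of E. coli, 4 from wild type and 4 from the hfq deletion strain. Hfq is a protein that binds small regulatory RNAs and helps them pair with messenger RNAs. The wild-type libraries A to D held 806978, 751203, 738564 and 723997 reads, and the deletion libraries A to D held 583829, 810238, 648809 and 752038. Deletion libraries C and D did not differ past the sampling noise (chi-square of 1.04 per degree of freedom, p = 0.0983) and were counted as 1 sample in means and SDs, except where all 4 deletion libraries are named. Of 4451 genes, 1705 had enough reads to be tested.

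The deleted gene was read first, as a check of the labels. The normalised hfq count was 114 ± 10.2 CPM in wild type (SD, n = 4) and 23.2 ± 2.44 in the deletion (SD, n = 3). Over all 4 deletion libraries it was 23.8 ± 3.98 (SD), a wider spread. In the fit with all 8 libraries the level was 4.77-fold lower (edgeR quasi-likelihood adjusted p = 2.72e-19). The 4 deletion libraries held 11, 17, 19 and 16 hfq reads and the 4 wild-type libraries 86, 93, 98 and 79. The reads left were 21.0% of the wild-type level over all 4 deletion libraries, and the files do not show where in the gene they lie. Among the neighbours of hfq, the downstream genes hflX, hflK and hflC fell by 0.46, 0.41 and 0.67 on the log2 scale, and the upstream tRNA modification gene miaA rose by 0.40. The fold changes of mutL, amiB and purA did not pass the threshold, at 0.02, -0.24 and -0.19. With library totals as the scale miaA did not pass (adjusted p = 0.0674) and purA did (adjusted p = 0.00946). In the DESeq2 Wald test hflX and hflK did not pass (adjusted p = 0.0509 and 0.0542), nor did hflX in edgeR without deletion library C (adjusted p = 0.0611).

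The comparison of deletion with wild type asked which transcripts change when Hfq is missing. The largest fall was in the small RNA McaS, from 60.5 ± 6.81 to 7.34 ± 2.98 CPM (SD, n = 4 and n = 3). The small RNAs MgrR and ChiX fell 5.91-fold and 5.89-fold. The largest rise, 12.2-fold, was in chiP, a chitoporin gene known to be repressed by ChiX, from 3.83 ± 1.05 to 44.8 ± 12.0 (SD, n = 4 and n = 3). Wild-type libraries A to D held only 3, 4, 3 and 2 chiP reads and deletion libraries A to D 16, 36, 41 and 36. The wild-type level is thus near the counting floor, and the size and rank of this rise are uncertain. The genes ygdQ and eptB, both known targets of MgrR, rose 4.88-fold and 3.39-fold. In all, 336 genes changed by edgeR's quasi-likelihood test, 203 higher and 133 lower in the deletion, and 63 of them changed at least 2-fold, 33 higher and 30 lower. The groups did not overlap for 356 of the 1705 genes, where chance gives a share of 2.86%. The balance of higher and lower calls depended on scaling. Library totals moved the median log2 fold change by -0.13 and gave 352 genes, 104 higher and 248 lower. Of the 336 calls, 237 were kept on that scale. No call among the 336 turned direction, but a shift of that size could turn only small changes. The DESeq2 Wald test gave 189, 110 higher and 79 lower.

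Among the other genes that rose most were mdtK, a multidrug efflux gene (3.27-fold), glcB, malate synthase G (3.10-fold), yciT (2.76-fold) and sslE (2.69-fold). The restriction enzyme gene hsdR rose 2.50-fold, the prolyl isomerase gene fkpB 2.34-fold and fabA, of unsaturated fatty acid synthesis, 2.33-fold. Among the genes that fell most were yjiY (4.10-fold), yahA (3.82-fold), yojI (3.34-fold), the mannose transporter gene manY (3.17-fold), exbB, of TonB-dependent uptake (3.15-fold), and cfa, cyclopropane fatty acid synthase (3.12-fold). The edgeR adjusted p of these 13 genes ran from 4.48e-20 for sslE to 0.000145 for fkpB.

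**Figure D1:**
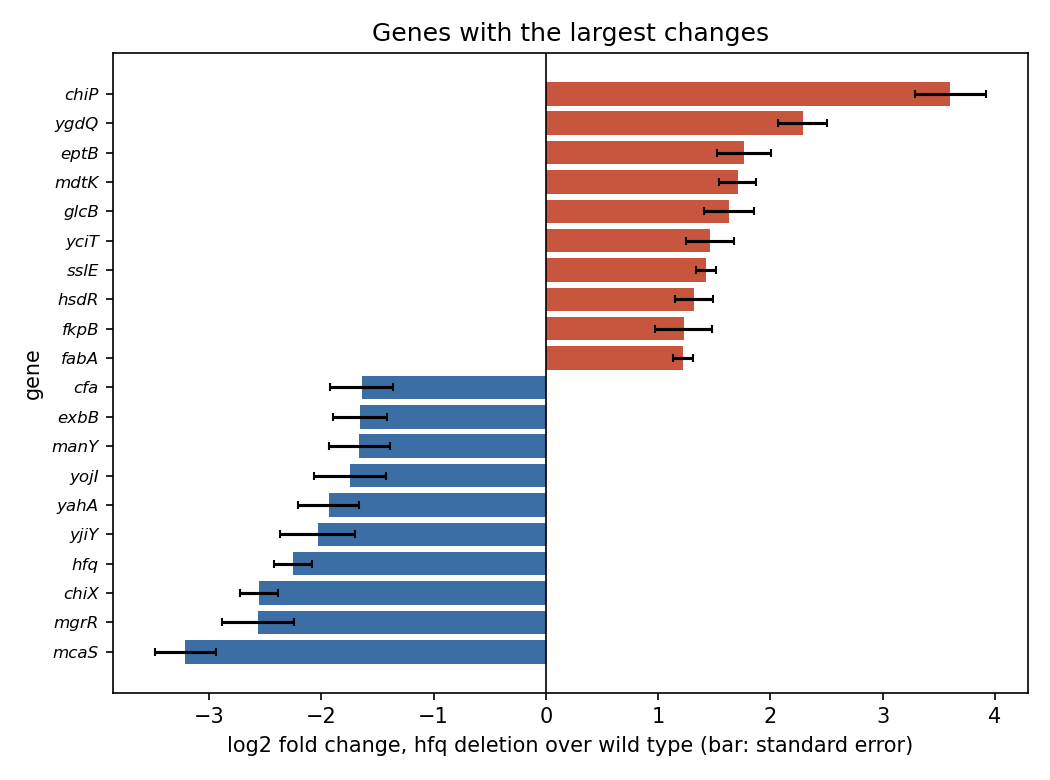
Horizontal bars give the log2 fold change of the deletion over wild type, with its standard error, for the 10 genes that rose most and the 10 that fell most. The bars run from -3.21 for mcaS to 3.60 for chiP.

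Of 7 small RNAs tested that bind Hfq, mcaS, mgrR, chiX and spf fell and gcvB rose, while glmZ and micA did not pass, at -0.29 and 0.60 on the log2 scale. With library totals glmZ passed, at -0.42 (adjusted p = 0.0256), and without deletion library B micA did, at 0.91 (adjusted p = 0.0326). Spot 42, the product of spf, was at 618 ± 76.6 CPM in wild type and 348 ± 56.7 in the deletion (SD, n = 4 and n = 3). GcvB, a regulator of amino acid and peptide uptake, rose 1.80-fold, from 170 ± 25.6 to 295 ± 38.3 (SD, n = 4 and n = 3). The list moved down by camera (adjusted p = 0.00315), a call that was lost with an estimated correlation (adjusted p = 0.234) and by camera on ranks (adjusted p = 0.112). Adjusted over the list alone, 5 fell and 1 rose. Another 17 members were below the filter. Their summed level was 94.2 ± 19.9 CPM in wild type and 34.3 ± 5.79 in the deletion (SD, all 4 deletion and all 4 wild-type libraries, exact permutation p = 0.0286, the smallest possible). With no filter, arcZ, rydC, dsrA, gadY and omrA fell in edgeR, from 37, 37, 53, 21 and 16 reads over the wild-type libraries to 4, 4, 15, 3 and 2. Among 14 stable and small RNAs not known to need Hfq, csrB, which sequesters the regulator CsrA, fell 2.57-fold, and ffs, the signal recognition particle RNA, rose 1.12-fold. The ffs call was lost in 8 alternatives, among them library totals (adjusted p = 0.815), DESeq2 (0.142), no filter (0.117) and leaving out wild-type library A, B or C or deletion library A (0.105, 0.0557, 0.13 and 0.0929).

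**Figure D2:**
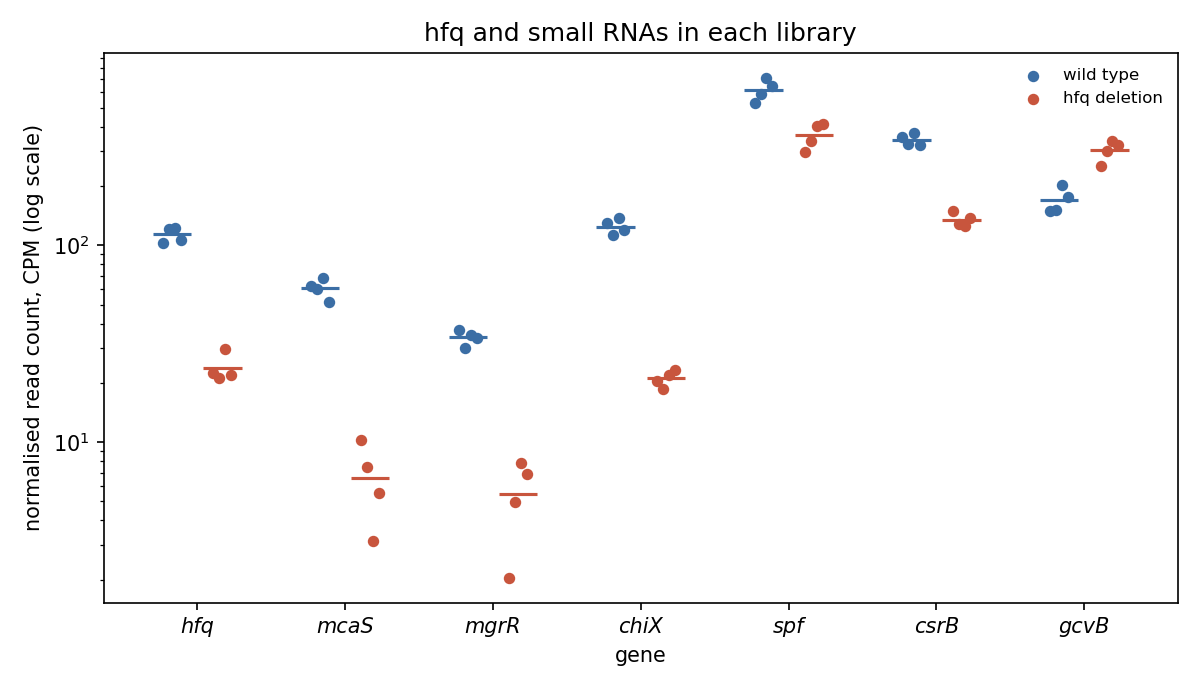
Points give normalised read counts (CPM) on a log axis in each of the 4 wild-type and 4 deletion libraries, with lines at the means of all 4 libraries of a group, for hfq and 6 small RNA genes. The groups do not overlap for any of the 7 genes, and gcvB is the one that is higher in the deletion.

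Amino acid and peptide uptake genes known as GcvB targets rose. Of 22 tested, 11 rose and 11 did not pass in edgeR, and 13 rose adjusted over the list alone. All of the 11 that rose in edgeR, apart from sstT, were dpp, opp or liv genes, so they may not be 11 separate targets. The dipeptide transporter gene dppA rose 2.07-fold, the serine and threonine transporter gene sstT 2.10-fold and the oligopeptide-binding protein gene oppA 1.66-fold. The list moved up by camera (adjusted p = 2.04e-06), with adjusted p = 0.0482 with an estimated correlation.

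Of 42 flagellar and chemotaxis genes tested, 29 rose and 13 did not pass in edgeR, 35 rose adjusted over the list alone, and the median log2 fold change was 0.44. Flagellin, fliC, rose 1.44-fold, from 2547 ± 59.6 to 3679 ± 31.4 CPM (SD, n = 4 and n = 3). The genes flgN and flgM, of an export chaperone and the anti-sigma factor of FliA, rose 2.20-fold and 2.07-fold. The list moved up by camera (adjusted p = 9.74e-15), with adjusted p = 0.00602 with an estimated correlation. With library totals 18 of the 42 rose.

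Of 27 respiratory genes tested, 14 fell, 2 rose and 11 did not pass. The genes that fell included the cytochrome bo gene cyoC (1.39-fold) and nuoB of NADH dehydrogenase I (1.83-fold), and 18 fell adjusted over the list alone. The count depended on scaling: 10 fell with upper-quartile scaling and 20 with library totals, and 2 rose with either. The cytochrome bd genes cydA and cydB rose 1.85-fold and 1.74-fold. The list moved down by camera (adjusted p = 5.62e-05), with adjusted p = 0.0271 with an estimated correlation. Of 16 heat shock genes, the protease gene lon fell 1.34-fold and the chaperone gene dnaK 1.13-fold, and 14 did not pass. With library totals 9 fell, and dnaK did not pass in DESeq2 (adjusted p = 0.0622). That list had adjusted p = 0.0431 by camera and adjusted p = 0.215 with an estimated correlation. Over the alternatives its adjusted p ran from 0.000803 to 0.215. The lowest was by fry, a list test that does not compare with other genes. By camera the list was lost without wild-type libraries A or D and without deletion libraries B, C or D, at 0.0683, 0.0700, 0.0644, 0.0714 and 0.0594. Upper-quartile scaling and removal of rRNA and tRNA genes also lost it (camera adjusted p = 0.0706 and 0.0738). It passed in 11 of 21 alternatives.

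**Figure D3:**
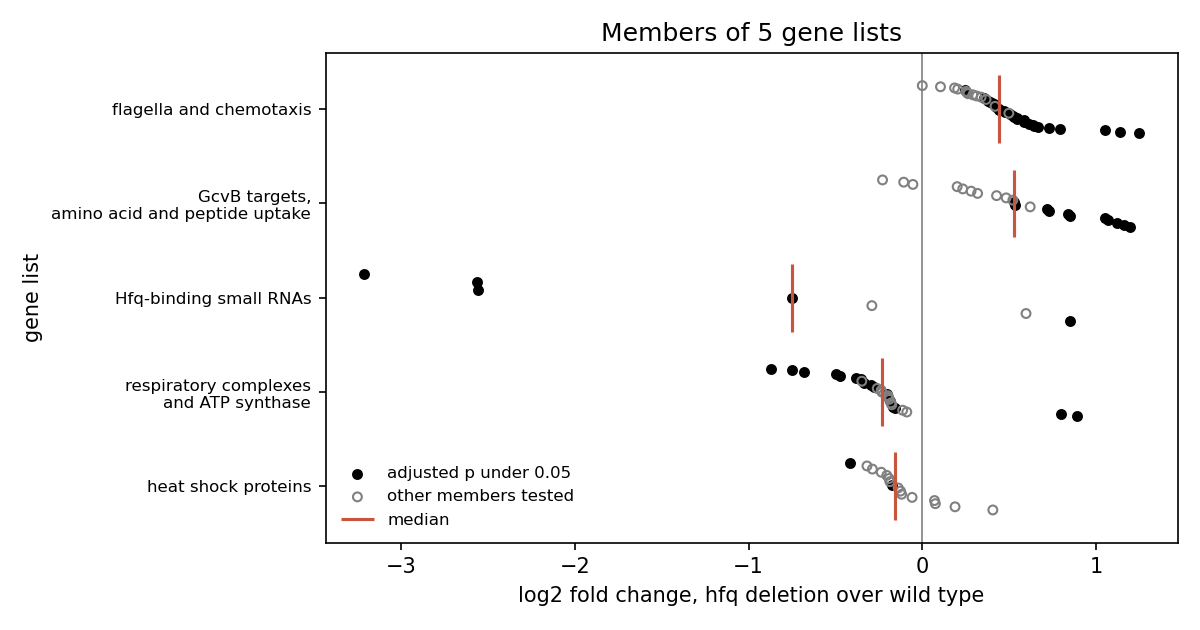
Each point is the log2 fold change of the deletion over wild type of 1 tested member of the 5 lists that moved by camera, filled where the adjusted p was under 0.05, with a line at the list's median. The medians are 0.44, 0.53, -0.75, -0.23 and -0.16 from top to bottom.

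The other 18 lists tested did not pass camera in the fit with all libraries and the preset filter and scaling. Some passed in alternatives. The branched-chain, histidine and tryptophan list did so in 5 of 20, the lowest camera adjusted p 0.000995 with no filter, in a range up to 0.395. The methionine and cysteine list passed with no filter and by fry (range 0.000232 to 0.738). The SgrS and RpoE lists passed in 4 and 2 of 21 (ranges 0.000789 to 0.261 and 0.0102 to 0.327). For both, 1 of these passes, and the lowest value, was by fry, which does not compare with other genes. The outer membrane, Spot 42 and stable RNA lists each passed in 1 of 21, by fry only (fry adjusted p = 0.000789, 0.0102 and 0.0279). Of 10 outer membrane genes, 5 rose, among them the porin gene ompC (1.73-fold), and ompT and nmpC fell (camera adjusted p = 0.107), against 2 higher and 3 lower with library totals. Of 21 RpoE genes, 6 rose, led by the anti-sigma factor gene rseA (2.08-fold), and 15 did not pass, with 7 higher adjusted over the list alone (camera adjusted p = 0.0779). Of 7 SgrS targets, the mannose genes manX, manY and manZ and asd fell, and ptsG rose (camera adjusted p = 0.0779), a rise not called with library totals or without deletion library A. Of 6 Spot 42 targets, maeA and sthA rose 2.19-fold and 2.21-fold and icd fell 1.23-fold (camera adjusted p = 0.275). Of 14 TCA cycle genes, acnB and mdh rose, and sucA, icd, sdhA, sdhB and fumA fell (camera adjusted p = 0.524), with sdhA lost without deletion library C (adjusted p = 0.0573). Of 6 genes tested in the list fixed as activated by small RNAs, rpoS, of the stationary-phase sigma factor, fell 1.74-fold and cfa fell. The genes shiA, glmS and ompF rose (camera adjusted p = 0.748 for the list). The rise of ompF is also among the 5 in the outer membrane list, fixed as genes under small RNA repression, so its placing here is uncertain. With library totals 1 of the 6 rose and 2 fell, and shiA did not pass in DESeq2 (adjusted p = 0.0777). Of 54 ribosomal protein genes 2 fell, rpsJ and rplB, neither of them adjusted over the list alone (camera adjusted p = 0.645). With library totals 17 fell and the list passed camera (adjusted p = 0.0448, in a range of 0.0448 to 0.908 over the alternatives), and with upper-quartile scaling 1 rose and 0 fell. Of 8 SOS genes 0 passed in edgeR, DESeq2 or limma-voom, with 3 higher in edgeR and in limma-voom and 0 in DESeq2 at an unadjusted p under 0.05, and 0 higher and 1 lower in edgeR with library totals. In the remaining lists, metK, metE, ilvC and leuA of amino acid synthesis fell, while metN, of methionine uptake, and carA and carB, of the arginine list, rose. The calls of metE, ilvC, leuA, metN and carA were each lost in DESeq2 (adjusted p = 0.115, 0.131, 0.164, 0.109 and 0.121) and in edgeR without at least 1 library, those of metN and carA without deletion library A (adjusted p = 0.0719 and 0.165). Calls also went both ways among sugar operons, and included rbsB higher and rbsD, gatY and gatZ lower, and the ribonuclease D gene rnd rose 2.13-fold. For arginine synthesis, stable RNAs, RyhB targets and genes activated by small RNAs, the median and the mean of the list differed in sign. Too few members for a list test were measured of the iron uptake list, where exbB, fhuA and exbD fell among 4, and of the RpoS regulon (2 tested), curli (1), acid resistance (0) and anaerobic respiration (4, of which napA rose, a call lost without deletion library A at adjusted p = 0.0647). In alternatives where 5 iron uptake genes were tested, that list's camera adjusted p, downward, ran from 0.00366 without wild-type library B to 0.0789 without wild-type library A, and with no filter it was 0.214 over 33 genes. With library totals, a scale that moves all genes down alike, the median changed sign in SOS, ribonucleases, stable RNAs, RyhB targets and the targets of FnrS, CyaR, MgrR and OmrAB. That of ribosomal proteins, near 0, changed sign with upper-quartile scaling and with rRNA and tRNA genes removed.

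RNA classes took slightly different shares of the reads. Ribosomal RNA made up 73.2% ± 0.699 in wild type (SD, n = 4) and 75.2% ± 1.79 in the deletion (SD, n = 3), a difference of 1.76 points over the 8 libraries (exact permutation p = 0.0286, Benjamini-Hochberg 0.0381 over 4 classes). Without deletion library A, with 77.3% rRNA, the difference was 0.986 points (exact permutation p = 0.0571), and without wild-type library A, B, C or D the exact permutation p was 0.114, 0.0857, 0.114 and 0.0857. Small RNAs took 0.968% ± 0.0391 and 0.830% ± 0.0687 (SD, n = 4 and n = 3, exact permutation p = 0.0286), and protein-coding genes 22.3% ± 0.540 and 20.4% ± 1.81 (SD, n = 4 and n = 3, exact permutation p = 0.0286). Without deletion library A the protein-coding difference was -0.965 points (exact permutation p = 0.0571), against -1.72, and without wild-type library A, B, C or D the exact permutation p was 0.0571, 0.0571, 0.0857 and 0.0571. The small RNA difference had exact permutation p = 0.0571 without wild-type library C. Transfer RNA took 3.37% ± 0.157 and 3.43% ± 0.203 (SD, n = 4 and n = 3, exact permutation p = 0.514). By gene, 30 of 86 tRNA genes rose and proM fell in edgeR, with a median log2 fold change of 0.18. With library totals 0 rose, 4 at an unadjusted p under 0.05, and the median was 0.05; DESeq2 called 6 higher and limma-voom 20, and without deletion library A 8 rose.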

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

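Tests chosen only after the result was seen were the counts over splits, apart from that of lists with an estimated correlation, the Fisher test on hfq, and the use of gcvB, gcvA and tRNA values against an explanation. The other scalings and the fits without a library were themselves planned. For the 336 changed genes, 1 of the 35 splits of the 8 libraries, the real one, gave as many, and the highest other split gave 0. The same holds for the 63 genes changed at least 2-fold (1 of 35, highest other 0). These counts argue against chance assignment of libraries to groups. The other splits mix the strains, which raises the spread within groups, so few calls are expected there. The splits cannot tell the genotype from another difference between the libraries of the strains. Chance assignment stays open for the number of lists: 3 of 35 splits moved at least 5 lists, and the highest other moved 7. With an estimated correlation the real split moved 3 lists and the highest other 0 (1 of 35). For each of the 5 lists the real split gave the smallest camera p (1 of 35). These 5 were picked because they passed in the real split, so that rank is not separate support. Camera with the preset correlation gave small p in other splits too, down to 1.33e-11 for the flagellar list against 4.24e-16 in the real split.

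Dixon's test on 170 groups of 4 values picked out 6 values, in 4 of the libraries, where chance gives about 8.5. Deletion library A stood apart for amiB at 20.5 CPM (the others at most 12.5), glcB at 61.6 (47.1 to 49.5) and napA at 61.6 (27.3 to 28.2). Wild-type library D was high for fabA at 198 (159 to 164), wild-type library B for mdh at 107 (94.3 to 95.9) and deletion library D for cyoC at 203 (185 to 188). The rise of napA did not pass without deletion library A, where its log2 fold change was 0.67.

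Reads of hfq remained in the deletion libraries at 21.0% of the wild-type level over all 4 deletion libraries. Wild-type RNA in those libraries would let no gene fall further than hfq. Among the 1705 genes tested, 4 had a larger fitted fall. Of these, mcaS had the lowest Fisher's exact p, 0.0157 on pooled reads and 0.0629 adjusted over the 4, so this explanation cannot be told apart. Genes below the filter were not in the Fisher test. With no filter, the small RNA genes arcZ, rydC, omrA, gadY and rprA had log2 fold changes of -2.84 to -2.33, against -2.25 for hfq with the filter. They rest on 2 to 4 pooled reads each in the deletion. The test takes pooled reads as independent molecules and covers counting error only. That outcome is fragile: 1 of the 4, ydjN, was not called as changed (wild-type reads 140, 12, 152 and 8), and adjusting over the other 3 would give 0.0472. Retained hfq sequence or flanking transcripts may also give such reads, and stays open because the files hold 1 total per gene.

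GcvB rose while mcaS, mgrR, chiX and spf fell. The lowest log2 fold change of gcvB over 4 other scalings was 0.72, against 0.85. Those scalings moved all genes nearly alike, by a median of -0.13 to 0.02, so a small gcvB value could not have come out. The scalings tried thus do not account for the rise, and a larger scaling error was not tested. Reads from the neighbouring gene gcvA are argued against, since gcvA changed by -0.562 CPM and gcvB gained 134, both over all 4 deletion libraries. The loss of Hfq itself stays open as the biological explanation, untested here.

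Of 86 tRNA genes, 30 were called higher in the deletion. With library totals 0 were called, which is consistent with the scaling of the libraries as a source but does not establish it, since that scale moves all genes alike by -0.13. Without deletion library A 8 were called, against 13 to 53 without each other library, so deletion library A alone may account for part of the calls. The median log2 fold change of the tRNA genes was 0.11 without it, against 0.18 with all libraries. Near-identical tRNA copies were not tested, and a biological effect of the genotype stays open.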

How the results depend on the processing

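No call among the 336 changed genes turned direction in any alternative run. That is a weak check, since other scalings moved all genes nearly alike and most fits shared most libraries. Of the 336 calls, 237 were kept with library totals, 323 with upper-quartile scaling and 328 with DESeq2 size factors. The filter of 20 reads in 4 libraries, which tested fewer genes, kept 266, and the fit without deletion library D kept 269. The DESeq2 Wald test gave 189 genes, 110 higher and 79 lower, and of the 336 genes 188 were called. The median dispersion was 0.0256 for the final values in DESeq2 and 0.00222 for the gene-wise values in edgeR. The edgeR test takes a quasi-likelihood dispersion rather than those gene-wise values, and whether the difference accounts for the fewer calls was not tested. Library totals gave 104 higher and 248 lower, through a median shift of -0.13. At least 2-fold, no filter gave 107 genes and a filter of 20 reads in 4 libraries gave 41, with 4396 and 1170 genes tested. Leaving out 1 library gave 289 to 360 genes, and 65 to 78 at least 2-fold. Lists that moved numbered 8 with no filter, 3 with an estimated correlation, 11 by fry, which does not compare with other genes, 4 with the replicate block, and 9, 7 and 4 with deletion C and D, B and D, or B, C and D summed, alternatives chosen after seeing the data; apart from the correlation and the fry test, the cause was not tested. Summing C and D gave 331 genes, B and D 329, and B, C and D 339. Leaving out 1 library, the rRNA difference ran from 0.986 to 2.09 points, that of small RNAs from -0.140 to -0.0944 and that of protein-coding genes from -2.09 to -0.965, and the cause of lost calls was not tested. Without rRNA in the total, the protein-coding difference was -1.05 points (exact permutation p = 0.257). Replicate letters did not pair the libraries: same-letter correlations were 0.02, 0.00293, 0.12 and -0.00917, and not every library correlated best with its own letter. With the letter as a replicate block 365 genes changed, 63 at least 2-fold, the heat shock list had adjusted p = 0.109, and the class differences of 1.76, -0.125 and -1.72 points had exact permutation p = 0.125, the smallest possible. Over the 80 named genes, 60 alternative fits lost a call, 5 gained one and 0 turned direction. Many lists had members with too few reads to pass the filter: 7 of 24 small RNAs that bind Hfq, 2 of 39 RpoS regulon genes and 0 of 14 acid resistance genes in the files were tested.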

Other observations

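The genes in this part were chosen after their values were seen, and no test was run on them as groups. The quinone-dependent malate dehydrogenase gene mqo had a log2 fold change of -1.43 ± 0.23 (SE, edgeR adjusted p = 6.99e-07), while mdh, of the NAD-dependent enzyme, was at 0.69 ± 0.11. The gluconeogenic gene ppsA fell by 1.18 on the log2 scale, and aceK, of the isocitrate dehydrogenase kinase, by 1.17. Of formate dehydrogenase O, fdoG fell by 0.77 and fdoH by 1.44.

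Threonine synthesis genes thrA, thrB and thrC fell by 0.60, 0.82 and 0.57 on the log2 scale. The glycine cleavage genes gcvH and gcvP rose by 1.44 and 1.04, and gcvT was at 0.67 with an edgeR adjusted p = 0.129. The transporter genes gltP, for glutamate, and uraA, for uracil, rose by 1.14 and 1.22. The fimbrial subunit gene fimA fell by 1.41. The mismatch repair gene mutS rose by 0.88 ± 0.15 (SE, edgeR adjusted p = 4.61e-06).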
